A study of Salmonella enterica subsp. enterica serovar Typhimurium str. SL1344 and Pseudomonas aeruginosa PAO1 with 149 samples.

How the data were processed

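RNA from sorted single bacteria and pools of 10 bacteria was amplified by MATQ-seq, and libraries were made with Nextera XT, per the labels' protocols. The Salmonella libraries were sequenced on a NovaSeq and the Pseudomonas libraries on a NextSeq. The series stated 60 Salmonella pools, 71 single Salmonella bacteria, 5 Pseudomonas pools and 13 single Pseudomonas bacteria, and the tables held a column for each. Per the submitters' processing notes, reads were checked with FastQC 0.11.7 and trimmed with cutadapt 1.9. They were aligned with STAR 2.5.4b at default settings (Salmonella to assembly ASM21085v2) and counted with featureCounts, version not given. HTSeq and DESeq2 are also named there, without a stated role. The deposited values are whole-number read counts per gene, not normalised, as made by the authors with featureCounts per the submitters' processing notes. Whether the counting used strand is not stated, so reads of a gene and of an antisense partner cannot be told apart. The study left out 5 Salmonella libraries as outliers of a principal component analysis of the 300 genes of highest variance, and set detection at more than 5 reads.

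The Salmonella table held 5219 features, of which 4668 matched a locus tag of the reference annotation (assembly ASM21085v2) and 2728 had a gene symbol. The other names are given as in the file. There were 475 features named only by an EBG identifier, which the reference does not hold. They took 24.5% of all reads, and EBG00001133739 alone took 23.9%. No feature could be identified as ribosomal or transfer RNA (0), so the planned removal of such features removed nothing. Total counts of the kept Salmonella libraries ran from 2835 to 7354220, and those of the Pseudomonas libraries from 28287 to 380827. At the lower totals most genes fall under the detection limit, so absence from a library was read as not detected at that depth.

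Groups were taken from the labels, and comparisons, tests, gene lists, the rule for named genes and a first group of other settings were fixed before the data were examined. The Salmonella pools were compared in 1 fit over 57 pools with edgeR 4.0.16 in R 4.3.3. This used TMM scaling, the robust quasi-likelihood test (two-sided) and Benjamini-Hochberg adjustment at a threshold of 0.05. It covered the 712 genes with more than 5 reads in at least 10 pools. TMM factors ran from 0.038 to 10.222 in anaerobic shock, 0.165 to 4.088 in NaCl shock and 0.047 to 8.042 in late stationary pools. The median dispersion was 8.91 (3.31 to 17.93), a wide spread between pools of a condition. A fold change is given on the log2 scale with its SE and with the first named condition over the second.

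Of 20 lists of Salmonella genes fixed beforehand, 15 had at least 3 tested members. They were tested as sets with camera of limma 3.58.1, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 45 tests. The other 5 lists, among them those for the SPI-1 and SPI-2 systems, had too few tested members. The number of detected genes per pool was compared by two-sided permutation tests with 100000 resamples, or by exact tests where a group held fewer than 10 pools, adjusted over 3 comparisons. Libraries were thinned to 24369 counts, the 10th percentile of Salmonella libraries, or to 119619, the 25th. The Pseudomonas libraries were thinned to 28287.

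Genes were named by rule. In each comparison these were the 6 genes of largest change in each direction among called genes detected in no fewer of the higher condition's pools than they were missed in, plus up to 3 members per list by adjusted p. After values were seen, the list members named were narrowed to those past the threshold, at most 2 per list in 8 lists, and the other lists were given as counts. In single bacteria the rule took the 3 genes per direction with the largest difference in the share of bacteria that detected them at 24369 counts. Summed counts have exact Poisson intervals and shares exact binomial ones, at the 95% level. A gene with 0 reads in a condition was set against a floor of 3 counts over the group. Where the lower condition held 1 to 3 reads, the ratio of summed CPM was given with an exact counting interval. Single bacteria were matched to the pools' mean log2 CPM profiles by Spearman correlation.

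The other settings fixed beforehand were DESeq2 size factors by poscounts and TMMwsp in place of TMM, no filter or filterByExpr, the Wald test of DESeq2 1.42.0, and limma-trend with a prior count of 2. More kept the 5 left-out libraries, added a term for title prefix, used M2 libraries alone or the 2 compared conditions alone, or left out the shallowest pools. Further settings were chosen after the data were seen. In these, features with EBG identifiers were left out, library size was the sole scaling, or detection was compared by Fisher's exact test. A carry-over filter set a count to 0 where it was below 0.2% of the gene's largest count among libraries that shared the row letter of its title, or its title prefix and column number. The limit of 0.2% was set above ratios already seen and no other was tried. Counts were compared unscaled for depth, so the filter could also remove real low counts from a shallow library. A cap held each gene at 10 times its median non-zero CPM, again the only value tried. Each named call was also fitted again without the pool of its largest count in the higher condition, with the same genes tested. Counts that may have been carried over from that pool into other libraries stayed in these fits. The share of a library's detected genes that belonged to a list was also added after the data were seen, compared by two-sided permutation tests and adjusted over 60 tests.

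The pool tests were tested on simulated counts with 200 changed genes. The genes were drawn independently and the changes balanced in direction, unlike the shifts seen in these data. For late stationary against NaCl shock (707 genes) edgeR recovered 16% of 8-fold changes, 69.4% of 32-fold, 96% of 128-fold and 100% of 512-fold, and called 2.36% of unchanged genes. For late stationary against anaerobic shock (709 genes) these were 26%, 66%, 94% and 96%, with 3.14% of unchanged genes called. For NaCl against anaerobic shock (709 genes) they were 20%, 68%, 94% and 100%, with 3.93% called. In the same order of comparisons, limma-trend recovered 6%, 4% and 4% of 8-fold and 83.7%, 84% and 82% of 512-fold changes. Fisher's exact test on detection recovered 22.4%, 8% and 14% of 512-fold changes. A low count of genes by that test therefore says little about the absence of change. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 gave the other values.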

Results

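RNA was sequenced from single bacteria and from sorted pools of 10 bacteria by MATQ-seq, a total-RNA method made for single cells. The bacteria were Salmonella enterica serovar Typhimurium SL1344, a gut pathogen, and Pseudomonas aeruginosa PAO1, an opportunistic pathogen. Salmonella was taken from 3 growth conditions, and the comparisons address how expression differs between them. Late stationary cultures were grown overnight in Lennox broth to an OD600 of 2.0. For the NaCl shock, cultures at an OD600 of 0.3 received 0.3 M NaCl for 10 min. For the anaerobic shock, cultures at an OD600 of 0.3 stood under mineral oil for 30 min. No library came from an unshocked culture at that OD600, so a difference between the shocks cannot be assigned to either one. Of 131 Salmonella libraries, the study left out 5 as outliers, and the other 126 entered the comparisons. They were 20 late stationary, 19 NaCl shock and 18 anaerobic shock pools, and 19, 23 and 27 single bacteria. Pseudomonas was taken after anaerobic shock alone, as 5 pools and 13 single bacteria. Nothing in the labels says that libraries of one condition came from separate cultures, so p-values measure only the spread between these pools, which may be technical.

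Depth differed between the conditions. Total counts ran from 25943 to 2104912 per late stationary pool (median 782573), from 668592 to 3012641 per NaCl shock pool (median 2216094) and from 31675 to 7354220 per anaerobic shock pool (median 1142896.5). Late stationary single bacteria held a median of 22795 counts (2835 to 521508). The medians were 675417 (4728 to 4094422) after NaCl shock and 1164087 (18938 to 3401291) after anaerobic shock. The feature EBG00001133739, which has no gene name in the sources used here, took a median of 51.1% of the counts of a late stationary pool, 14.7% of a NaCl shock pool and 18.9% of an anaerobic shock pool. The letter and digit that open each library title (M1, M2 or M3) were treated as a batch. Late stationary pools were 16 M1 and 4 M2, NaCl shock pools 16 M2 and 3 M3, and anaerobic shock pools 7 M2 and 11 M3.

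Late stationary pools showed the fewest genes. A gene was called detected at more than 5 reads, the limit the study states. The late stationary pools held 192 ± 69.2 detected genes (SD, n = 20), the NaCl shock pools 637 ± 197 (n = 19) and the anaerobic shock pools 424 ± 160 (n = 18). Late stationary pools were lower than NaCl shock pools (adjusted p = 3e-05) and than anaerobic shock pools (adjusted p = 3e-05) in two-sided permutation tests, adjusted over the 3 comparisons. The smallest p these permutations can give is 2e-05. NaCl shock pools were higher than anaerobic shock pools (adjusted p = 0.00136). With every pool thinned to 24369 counts the means were 55.8 ± 47.8, 277 ± 92.1 and 214 ± 77.5. Among M2 pools alone they were 204 ± 93.1 (n = 4), 683 ± 177 (n = 16) and 517 ± 156 (n = 7), and the difference between NaCl and anaerobic shock pools no longer passed (adjusted p = 0.0558, exact permutation test). In thinned M2 pools late stationary pools passed against NaCl shock (adjusted p = 0.0211) but not against anaerobic shock (adjusted p = 0.0545, exact permutation tests).

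**Figure D1:**
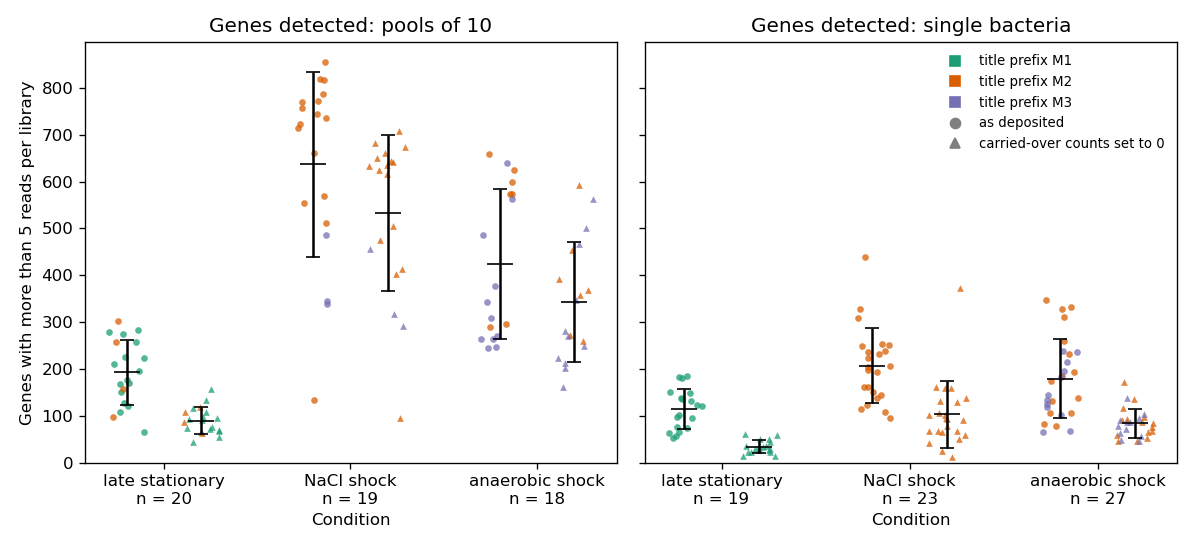
Genes detected with more than 5 reads per library (vertical axis) in Salmonella pools of 10 and single bacteria of each condition, each point a library and each bar a mean with its SD. The means of the pools are 192 for late stationary, 637 for NaCl shock and 424 for anaerobic shock, and those of the single bacteria 115, 207 and 179.

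NaCl and anaerobic shock pools differed in genes of anaerobic metabolism, and single genes of osmotic and general stress also differed. The propionate kinase gene tdcD, of anaerobic threonine breakdown, was detected in 12 of 18 anaerobic shock pools and in 0 of 19 NaCl shock pools. Its log2 fold change (NaCl over anaerobic shock) was -10.79 ± 1.53 (SE; edgeR's adjusted p = 1.26e-07). The NaCl shock pools held 2 of its reads, and the ratio of summed counts was 2750 (counting interval 760 to 22700), or 1530 (422 to 12600) without anaerobic shock pool replicate 5. tdcD lies at positions 3429465 to 3430673 of the chromosome in assembly ASM21085v2. Next to it lies a pyruvate formate-lyase gene annotated as pflB (SL1344_3213, 3427137 to 3429431), which was detected in 15 of 18 anaerobic against 4 of 19 NaCl shock pools (-11.37 ± 2.19, edgeR's adjusted p = 4.26e-05). Also lower after NaCl shock were hybO, the small subunit of a hydrogenase (-12.51 ± 1.77), dmsA, the catalytic subunit of dimethyl sulfoxide reductase (-10.03 ± 2.25), and pduA, a shell protein of the propanediol-degrading microcompartment (-10.13 ± 1.80). With counts that may have been carried over set to 0, hybO was detected in 8 of 18 anaerobic and 4 of 19 NaCl shock pools. There pflB (SL1344_3213) was detected in 13 and 1, dmsA in 13 and 0 and pduA in 8 and 0.

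The list of genes for anaerobic respiration and fermentation was lower as a set after NaCl shock. Of its 30 tested members 19 were lower and 3 higher, and the counts adjusted over the list alone were also 19 and 3. The set passed camera (adjusted p = 2.14e-18) and held with an estimated correlation (adjusted p = 2.09e-05). The list made up 2.22% ± 0.735 of the genes detected in a NaCl shock pool and 6.11% ± 2.26 of those in an anaerobic shock pool (adjusted p = 0.0012, permutation test). Among M2 pools these shares were 2.27% ± 0.779 (n = 16) and 5.21% ± 1.95 (n = 7; adjusted p = 0.00587, exact permutation test).

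Single genes of the osmotic and general stress lists were higher after NaCl shock. osmY, which encodes a periplasmic protein induced by salt and by the stress factor RpoS, was detected in 17 of 19 NaCl shock and 7 of 18 anaerobic shock pools (log2 fold change 7.48 ± 1.74, edgeR's adjusted p = 0.000489). proX, the binding protein of the ProU glycine betaine transporter, was detected in 9 of 19 against 1 of 18 pools (8.55 ± 1.76, edgeR's adjusted p = 0.000118). elaB, a membrane protein gene of the RpoS list, was detected in 19 of 19 against 10 of 18 pools (7.69 ± 1.73). Of 10 tested members of the RpoS list, 7 were higher and 0 lower (8 and 0 adjusted over the list alone). That set passed camera (adjusted p = 0.000638), but not with an estimated correlation (adjusted p = 0.252). Of 8 tested members of the list for osmoprotection and potassium uptake, 6 were higher and 0 lower (also 6 and 0 adjusted over the list alone), and the set did not pass (camera, adjusted p = 0.191). Among M2 pools 3 of 9 RpoS list genes were higher (camera, adjusted p = 0.0167, and 0.605 with an estimated correlation) and 1 of 6 osmoprotection genes (camera, adjusted p = 0.479). osmY is in both lists. At 24369 counts per pool, the osmoprotection list made up 1.11% ± 0.596 of the genes detected in a NaCl shock pool and 0.382% ± 0.349 of those in an anaerobic shock pool (adjusted p = 0.0012, permutation test). The RpoS list made up 1.83% ± 0.713 and 0.697% ± 0.807 (adjusted p = 0.00144, permutation test). At full depth neither difference in share passed (adjusted p = 0.0764 and 0.214, permutation tests), nor among M2 pools (0.385 and 0.211). With counts that may have been carried over set to 0 that of the osmoprotection list did (0.0386) and that of the RpoS list did not (0.099). proW, whose counts did not rise with depth, is in the osmoprotection list, and its part in the share was not separated.

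Other genes were higher after NaCl shock. ssaA was detected in 15 of 19 NaCl shock and 1 of 18 anaerobic shock pools (log2 fold change 9.78 ± 1.62, edgeR's adjusted p = 8.3e-06). fruB, of fructose uptake, was detected in 17 of 19 and 4 of 18 (9.28 ± 1.61, edgeR's adjusted p = 1.12e-05). The cell division gene damX (14.31 ± 2.46), the GTPase gene typA (9.63 ± 2.85), nuoA of respiratory complex I (9.30 ± 1.95) and alaC, an alanine-forming transaminase (9.10 ± 1.71), were also higher. Of 25 tested members of the list for aerobic respiration and the TCA cycle 11 were higher and 2 lower (11 and 2 adjusted over the list alone), cyoE of haem O synthesis among the higher (7.48 ± 1.70). The set did not pass (camera, adjusted p = 0.494). Of 39 ribosomal protein genes 8 were higher and 0 lower (5 and 0 adjusted over the list alone), rpsH (5.60 ± 1.45) and rplN (5.49 ± 1.51) among them. That set passed camera (adjusted p = 0.0028), but not with an estimated correlation (adjusted p = 0.413) nor among M2 pools, where 1 of 34 members was higher (camera, adjusted p = 0.778). The protease genes clpP (6.98 ± 1.78) and hslU (5.38 ± 1.49), the flagellin methylase gene fliB (7.90 ± 1.95) and the outer membrane gene ompX (4.17 ± 1.44) were higher. The chemoreceptor gene tcp (-6.41 ± 1.71), the porin gene ompD (-4.49 ± 1.54) and sifA, a secreted effector of the SPI-2 system (-9.11 ± 1.91), were lower.

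Each gene named above was also fitted without the pool of its largest count in the higher condition, a setting chosen after the data were seen. Counts that may have been carried over from that pool into other libraries stayed in. Without anaerobic shock pool replicate 8, which held 99.6% of the anaerobic shock reads of sifA, its log2 fold change was -1.74 ± 1.23 and no longer passed, and pduA stood at -7.98. Without replicate 14 ompD stood at -1.88 ± 1.27 and no longer passed, hybO at -5.77 and pflB (SL1344_3213) at -7.08. Replicate 14 had the lowest TMM factor of the anaerobic shock pools (0.038). Without NaCl shock pool replicate 6 damX stood at 8.40 and typA at 4.97, without replicate 5 elaB at 6.22, osmY at 5.38 and clpP at 4.38, and without replicate 20 fliB at 4.63. NaCl shock pool replicate 6 had the lowest TMM factor of its condition (0.165). A low factor raises a pool's scaled counts, so fold changes that rest on such a pool depend on the scaling. The values of the other genes named for this comparison moved by less than 1 on the log2 scale and passed, tdcD among them at -10.12.

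In all, 281 of 712 tested genes differed between NaCl and anaerobic shock pools (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these 199 were higher and 82 lower in NaCl shock, against a median log2 fold change of 1.42 over the 712 genes. Among M2 pools alone 75 of 438 tested genes passed, 47 higher and 28 lower. There 11 of 16 tested members of the anaerobic list were lower and 0 higher, and the set passed camera (adjusted p = 1.04e-12, and adjusted p = 0.00074 with an estimated correlation). The count was 162 without the shallowest pools and 70 once counts that may have been carried over between libraries were set to 0. It was 78 once each gene's highest counts were capped, where typA, nuoA, sifA, fliB, cyoE, rpsH, rplN, clpP, hslU, ompD and ompX no longer passed.

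**Figure D2:**
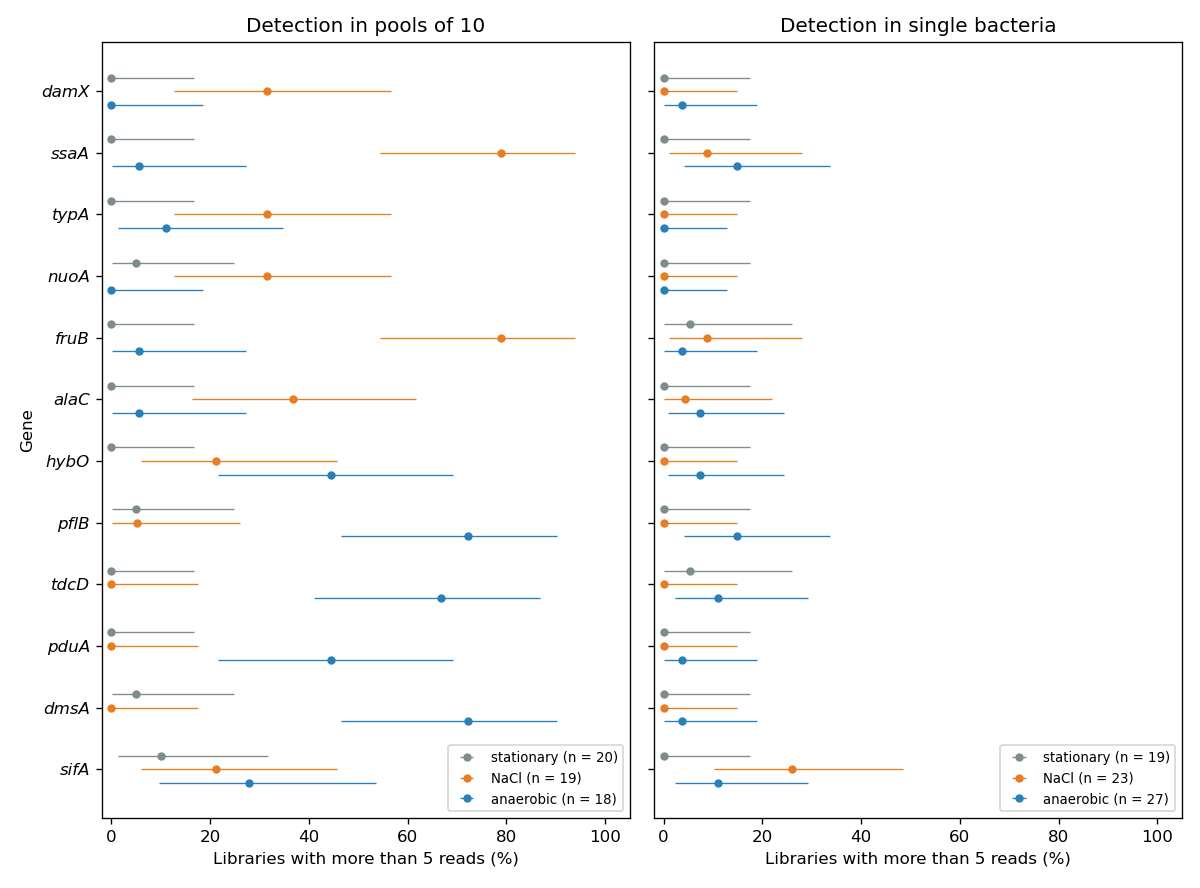
Share of libraries (percent, horizontal axis, exact 95% intervals) in which each of the 12 genes of largest change between NaCl and anaerobic shock pools was detected, after counts that may have been carried over between libraries were set to 0, for pools of 10 and for single bacteria of each condition. In pools, tdcD is at 66.7% after anaerobic shock and 0% in both other conditions.

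Of the 712 tested genes, 356 were lower in late stationary than in NaCl shock pools. Of 39 tested ribosomal protein genes, 32 were lower in late stationary pools and 2 higher, the same counts as adjusted over the list alone. rplJ was detected in 9 of 20 late stationary and 19 of 19 NaCl shock pools (log2 fold change, late stationary over NaCl shock, -7.29 ± 1.60, edgeR's adjusted p = 0.000246). rpsA was detected in 6 of 20 and 19 of 19 (-5.72 ± 1.28, edgeR's adjusted p = 0.000312). The carbonic anhydrase gene can was detected in 10 of 20 against 19 of 19 pools (-9.37 ± 1.83, edgeR's adjusted p = 8.36e-05). The ribosomal set was lower (camera, adjusted p = 1.57e-05), but not with an estimated correlation (adjusted p = 0.252). With a term for title prefix it passed camera (adjusted p = 0.0377, and 0.706 with an estimated correlation), and among M2 pools it did not (adjusted p = 0.412). No ribosomal gene was among the few genes past edgeR's threshold in either setting.

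The salt-responsive genes osmY (-7.06 ± 1.63) and osmE (-7.62 ± 1.73) were also lower in late stationary pools. osmE was detected in 0 of 20 late stationary and 9 of 19 NaCl shock pools, and with 3 reads over the late stationary pools the ratio of summed counts was 730 (counting interval 250 to 3540). Further genes lower in late stationary pools were aroB of the shikimate pathway (-12.45 ± 2.33), typA (-11.31 ± 2.73), damX (-11.29 ± 2.14), the methyltransferase gene pglX (-9.34 ± 1.86), fliB (-8.60 ± 1.93), nuoG of respiratory complex I (-8.37 ± 1.93) and cyoE (-7.54 ± 1.62). Of 10 tested chaperone and heat shock protease genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone), with clpP at -9.10 ± 1.86 and hslV at -7.30 ± 1.71. The set did not pass (camera, adjusted p = 0.0643). The outer membrane genes tolC (-5.76 ± 1.40) and ompX (-4.37 ± 1.39) were lower. Of 25 aerobic respiration genes 12 were lower and 3 higher, and of 16 tested flagellar and chemotaxis genes 7 were lower and 4 higher. Of 10 RpoS list genes 5 were lower and 1 higher, and of 8 osmoprotection genes 4 were lower and 0 higher. Adjusted over the list alone, none of these 4 pairs of counts changed. None of the 4 sets passed camera, with adjusted p = 0.826, 0.494, 0.171 and 0.94.

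Fewer genes were higher in late stationary than in NaCl shock pools. Of 30 tested anaerobic list genes 9 were higher and 4 lower (9 and 3 adjusted over the list alone). Among them were the dimethyl sulfoxide reductase genes dmsA (14.08 ± 2.27, edgeR's adjusted p = 1.24e-05) and dmsB (14.95 ± 2.75, edgeR's adjusted p = 5.44e-05), which were detected in 7 and 4 of 20 late stationary and 4 and 2 of 19 NaCl shock pools. Late stationary pool replicate 7 held 99.9% of the late stationary reads of dmsA and of dmsB, and with counts that may have been carried over set to 0 each was detected in 1 of 20 and 0 of 19 pools. The set was higher (camera, adjusted p = 0.00749), but not with an estimated correlation (adjusted p = 0.379), with a term for title prefix (adjusted p = 0.439) or among M2 pools (adjusted p = 0.134). Its median log2 fold change was -0.01 and its mean 0.94, against a median of -3.07 over all 712 genes (-3.01 with the 3 genes at 0 reads in 1 condition set at their bounds). With counts capped and counts that may have been carried over set to 0, 1 of its 21 tested members was higher and 14 were lower. Also higher were rpoC of RNA polymerase (5.23 ± 1.65), the glycerol genes glpK (4.48 ± 1.58) and glpD (3.32 ± 1.43), malE of maltose uptake (3.54 ± 1.44), frdA of fumarate reductase (3.44 ± 1.43) and golT, a metal efflux gene (3.19 ± 1.15). The chemoreceptor gene tcp (8.62 ± 1.88) was higher but detected in 3 of 20 late stationary pools. Over all libraries the median count of golT was no higher in deep than in shallow ones, so its difference is not read as expression. With a term for title prefix the sign of rpoC, malE, frdA, glpD and dmsB turned negative, and with counts capped none of rpoC, glpK, malE, frdA, glpD and golT passed.

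Without the late stationary pool of its largest count, the log2 fold change was 2.70 ± 1.43 for rpoC (without replicate 8), 1.91 ± 1.31 for glpK (6), 0.98 ± 1.25 for malE (12), 2.51 ± 1.38 for glpD (13) and -2.03 ± 1.20 for frdA (15), and none of them passed. dmsA stood at 3.89 and dmsB at 3.68 without replicate 7, and tcp at 3.17 without replicate 12, and these 3 passed. Replicate 7 had the lowest TMM factor of the late stationary pools (0.047), which raised its scaled counts. Counts that may have been carried over from the pool left out stayed in. dmsA and dmsB had each fallen to 1 of 20 late stationary pools with such counts set to 0, so passing here does not support them. Of the lower genes, aroB stood at -5.78, typA at -6.65, damX at -5.38 and can at -5.99 without NaCl shock pool replicate 6. That pool had the lowest TMM factor of the NaCl shock pools (0.165). Without replicate 5 clpP stood at -6.50 and osmY at -4.96, and without replicate 20 fliB at -5.32 and nuoG at -4.63. All of these lower genes passed, and the other genes named for this comparison moved by less than 1 and passed.

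Between late stationary and NaCl shock pools 487 of 712 genes passed edgeR's test, 131 higher and 356 lower in late stationary, or 55 and 420 with library size as the sole scaling. With a term for title prefix 4 genes passed, and among M2 pools alone, with 4 late stationary pools, 2. The median SE of a gene was 3.20 with the term and 2.76 in M2 pools, against 1.51 without. Of the 356 lower genes 355 were negative with the term, at a median log2 fold change of -6.08 against -5.47 without it. Of the 236 of them tested in M2 pools 234 were negative there, at a median of -4.55 (-4.45 with genes at 0 reads in 1 condition set at their bounds). Of the 131 higher genes 44 were positive with the term, and 21 of the 58 tested in M2 pools, at medians of -2.66 and -1.70 against 5.58 without it. The median over all tested genes was -5.14 with the term and -3.85 in M2 pools (-3.70 with bounds). With the term 619 of the 712 genes were negative, so the kept signs of the lower genes say little about prefix. With counts that may have been carried over set to 0, 18 genes were higher and 321 lower.

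Against anaerobic shock, late stationary pools showed lower counts of anaerobic metabolism. Of 30 tested members of the anaerobic list 19 were lower and 4 higher, as they were when adjusted over the list alone. The set was lower (camera, adjusted p = 3.11e-11), also with an estimated correlation (adjusted p = 0.00102). phsA, a thiosulfate reductase gene, had 0 reads in the 20 late stationary pools and was detected in 9 of 18 anaerobic shock pools, which makes it at least 4530-fold lower in late stationary pools, against a floor of 3 counts over the group. Anaerobic shock pool replicate 10 held 98.9% of its reads, and without that pool it was at least 59.5-fold lower. The other anaerobic shock pools held 268 of its 23350 reads. These were not separated from reads carried over from replicate 10, so both the pools that detected phsA and the second bound may rest on 1 pool. hybO was detected in 5 of 20 late stationary and 15 of 18 anaerobic shock pools (log2 fold change, late stationary over anaerobic shock, -12.04 ± 2.27, edgeR's adjusted p = 0.000115). pflB (SL1344_3213) was detected in 2 of 20 and 15 of 18 (-9.46 ± 2.00, edgeR's adjusted p = 0.000225), and the lysine decarboxylase gene cadA in 5 of 20 and 17 of 18 (-10.60 ± 1.97, edgeR's adjusted p = 0.000115). The list made up 3.75% ± 1.95 of the genes detected in a late stationary pool, below the 6.11% ± 2.26 of an anaerobic shock pool (adjusted p = 0.0264, permutation test). Among M2 pools the difference, 2.98% ± 0.997 (n = 4) against 5.21% ± 1.95 (n = 7), did not pass (adjusted p = 0.231, exact permutation test). With counts that may have been carried over set to 0 it passed among M2 pools, at 1.55% against 5.76% (n = 4 and 7; adjusted p = 0.0303, exact permutation test). There the filter took late stationary pools from 204 to 94.2 detected genes and anaerobic shock pools from 517 to 385. The part of the filter in this difference was not tested.

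Other genes lower than after anaerobic shock were ubiK of ubiquinone synthesis (-11.00 ± 2.29), sdhC of succinate dehydrogenase (-10.28 ± 2.05), the flagellar gene fliM (-7.90 ± 1.83), the porin gene ompD (-5.98 ± 1.62), the chaperone gene dnaK (-5.42 ± 1.35), rplW (-5.38 ± 1.39) and tolC (-2.92 ± 1.24). The flagellar gene flgA (-6.88 ± 1.54) had 2 reads over the late stationary pools, a ratio of 702 (counting interval 194 to 5800), or 286 (79.0 to 2370) without anaerobic shock pool replicate 5. Of 39 ribosomal protein genes 19 were lower and 3 higher (20 and 3 adjusted over the list alone), and the set did not pass (camera, adjusted p = 0.494).

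Single general stress genes were higher in late stationary than in anaerobic shock pools. rpoS itself was higher (12.64 ± 2.59, edgeR's adjusted p = 0.000146), though detected in 6 of 20 against 2 of 18 pools. The trehalose synthesis gene otsA was higher too (9.54 ± 2.28), and detected in 7 of 20 against 3 of 18. Of 10 tested RpoS list genes 5 were higher and 1 lower, as adjusted over the list alone. The set passed camera (adjusted p = 0.0436), but not with an estimated correlation (adjusted p = 0.413), with a term for title prefix (adjusted p = 0.306) or among M2 pools (adjusted p = 0.203). With counts capped 2 members were higher and 1 lower, and with counts that may have been carried over also set to 0 the balance turned, to 1 higher and 4 lower of 9. Also higher were the glycerol genes glpD (6.54 ± 1.71) and glpK (4.17 ± 1.59), rpoC (6.79 ± 1.82), tuf (SL1344_3412, 3.78 ± 1.40) and aceE of pyruvate dehydrogenase (3.74 ± 1.61). Further genes higher were fumC (8.91 ± 2.05), putA (7.12 ± 2.00), rpsB (7.39 ± 1.87), ftsH (2.97 ± 0.79) and nadR (2.49 ± 1.08). tuf has a near-identical copy (SL1344_4085), so how reads divide between the copies is uncertain. The median count of nadR was no higher in deep than in shallow libraries, so its difference is not read as expression.

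The same refit was made for this comparison. phsA, with its 0 reads in late stationary pools, passed without anaerobic shock pool replicate 10 (edgeR's adjusted p = 0.000245), and its size is given by the bound above. Of the genes higher in late stationary pools, glpK stood at 1.59 ± 1.32 (without replicate 6), rpsB at 1.01 ± 1.22 (17), nadR at 2.43 ± 1.09 (16), tuf at -1.01 ± 1.10 (7), aceE at -1.77 ± 1.36 (2) and putA at -0.57 ± 1.32 (4), and none passed. rpoS fell from 12.64 to 5.05 without late stationary pool replicate 8, which held 99.7% of its late stationary reads, and otsA to 3.66 without replicate 13, which held 98.2%. Counts that may have been carried over from the pool left out stayed in here too. That phsA, rpoS and otsA passed therefore does not by itself support them. rpoC stood at 4.25 and fumC at 7.77 without replicate 8. Without anaerobic shock pool replicate 14 hybO stood at -5.30, ubiK at -4.02, cadA at -5.77, sdhC at -2.88, pflB (SL1344_3213) at -5.17 and ompD at -3.37. That pool had the lowest TMM factor of the anaerobic shock pools (0.038). flgA stood at -4.79 without replicate 5 and fliM at -4.65 without replicate 8. tolC stood at -2.36 ± 1.21 without replicate 10 and no longer passed. The rest of the genes moved by less than 1 and passed.

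Between late stationary and anaerobic shock pools 410 of 712 genes passed edgeR's test, 163 higher and 247 lower in late stationary, 73 and 364 with library size as the sole scaling, or 32 and 305 with counts that may have been carried over set to 0. The median log2 fold change over the 712 genes was -1.09. With a term for title prefix 2 genes passed and among M2 pools alone 2, none of them of the anaerobic list, at a median SE of 3.13 and 2.75 against 1.47 without the term. Of the 247 lower genes 233 were negative with the term (median -5.79 against -5.13 without it), as were 147 of the 158 tested in M2 pools (median -5.18, or -4.95 with bounds). Of the 163 higher genes 75 were positive with the term and 42 of the 87 tested in M2 pools, at medians of -0.27 and -0.26 against 6.58. The median over all tested genes was -3.14 with the term and -2.89 in M2 pools (-2.49 with bounds). With the term 522 of the 712 genes were negative, so kept signs say little about prefix here too. All 19 lower genes of the anaerobic list were negative with the term, and the median of the list was -7.47 (-7.72 with bounds) against -5.43. In M2 pools it was -5.94. The anaerobic set stayed lower with that term (camera, adjusted p = 3.14e-07, and adjusted p = 0.0328 with an estimated correlation), and in M2 pools (camera, adjusted p = 3.13e-05, but adjusted p = 0.0595 with an estimated correlation). With the term the signs of rpoC, glpD, tuf, aceE, putA, fumC and ftsH turned negative and that of sdhC positive, and glpK, nadR and rpsB changed sign under other settings.

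**Figure D3:**
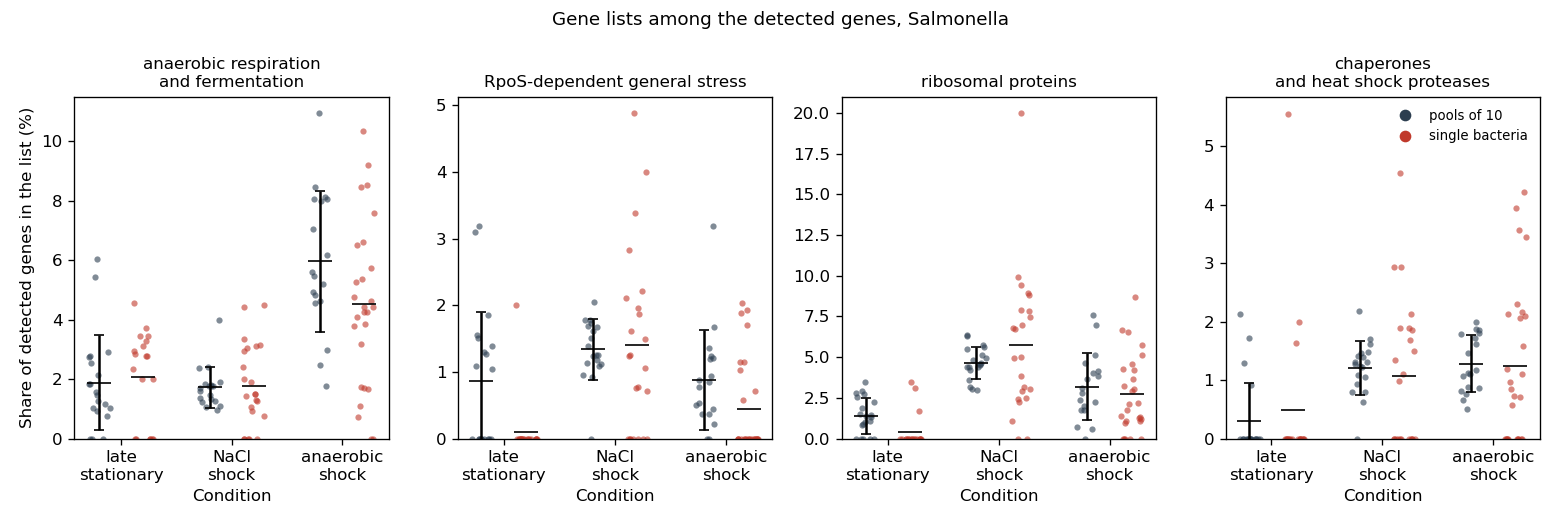
Share of each library's detected genes (percent, vertical axis) that belonged to the lists for anaerobic respiration, RpoS-dependent stress, ribosomal proteins and chaperones, by condition, after counts that may have been carried over between libraries were set to 0. Each point is a library. Bars show the mean and SD of pools, and a mark shows the mean alone of single bacteria. In pools the anaerobic list averages 1.87% in late stationary, 1.72% in NaCl shock and 5.96% in anaerobic shock.

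No test was made between conditions in single bacteria, since cells are not replicates. The labels name no culture for single bacteria or for pools, so the tests above compare pools and not cultures. At 24369 counts per bacterium, sodA, the superoxide dismutase gene, was detected in 13 of 21 NaCl shock bacteria (61.9%, exact 95% interval 38.4 to 81.9), 1 of 26 anaerobic shock bacteria (3.85%, 0.0973 to 19.6) and 0 of 9 late stationary bacteria (upper bound 33.6%). can was detected in 12 of 21 (57.1%, 34.0 to 78.2), 1 of 26 and 0 of 9, and the ribosomal gene rpsJ in 12 of 21 and 1 of 26. The ribose-binding protein gene rbsB was detected in 11 of 26 anaerobic shock bacteria (42.3%, 23.4 to 63.1), 2 of 21 NaCl shock bacteria and 1 of 9 late stationary bacteria. ompD was detected in 8 of 26 anaerobic shock, 2 of 9 late stationary and 0 of 21 NaCl shock bacteria, and the aspartase gene aspA in 14 of 26 and 6 of 21. gapA of glycolysis was detected in 17 of 21 NaCl shock, 12 of 26 anaerobic shock and 2 of 9 late stationary bacteria. The pflB gene SL1344_0910 was detected in 11 of 26 anaerobic shock and 1 of 9 late stationary bacteria. Shallower bacteria were left out, 10 late stationary, 2 NaCl shock and 1 anaerobic shock.

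Sums over bacteria of all depths put the same condition highest as detection did for sodA, rbsB and ompD, but ranked the lower conditions of sodA and rbsB the other way. sodA stood at 6580 CPM after NaCl shock (exact Poisson 95% interval 6540 to 6610), 12.9 (11.7 to 14.2) after anaerobic shock and 84.2 (70.2 to 100) in late stationary bacteria. rbsB stood at 267 CPM (260 to 274), 13900 (13900 to 14000) and 115 (98.8 to 134) in the same order. ompD was at 2.69 CPM (2.04 to 3.49) after NaCl shock against 12700 after anaerobic shock. These intervals, like the floors and shares above, cover counting error only, since PCR reads without molecular identifiers are not independent molecules. tdcD was detected at full depth in 0 of 23 NaCl shock bacteria (upper bound 14.8%) and in 4 of 27 anaerobic shock bacteria (14.8%, 4.19 to 33.7).

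The genes with the largest excess in late stationary bacteria at 24369 counts were proW (7 of 9 against 1 of 21 and 1 of 26), nadR (5 of 9 against 1 of 21), fldA (8 of 9 against 8 of 26), nrfEF (9 of 9 against 11 of 26) and hypE (5 of 9 against 1 of 21). The median counts of proW, nadR, fldA and nrfEF were no higher in deep than in shallow libraries. Such a count makes up a larger share of a shallow library, and late stationary bacteria were the shallowest. The excesses of these genes are therefore not read as higher expression. hypE was not among the 27 genes checked for this, so its excess is left open.

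Most genes that differed between pools went the same way in the sums over single bacteria. The direction was shared by 304 of 479 genes for late stationary against NaCl shock (63.5%, exact 95% interval 59.0 to 67.8). For late stationary against anaerobic shock it was shared by 243 of 404 (60.1%, 55.2 to 65.0). For NaCl against anaerobic shock it was shared by 190 of 278 (68.3%, 62.5 to 73.8). Genes of the same pools are not independent, so these intervals may be too narrow. By sums, 230 of 352 genes lower and 74 of 127 higher in late stationary than in NaCl shock pools shared the direction. Such unequal numbers can raise the matches expected by chance. That level was not computed, so none of these shares is read as above chance. By the share of bacteria with more than 5 reads, 242 of 303 genes lower in late stationary than in NaCl shock pools shared the direction, and 36 of 104 of the higher ones. This share was taken at full depth, at a median of 22795 counts in late stationary and 675417 in NaCl shock bacteria. The split therefore cannot be told apart from depth. Across the 712 genes, which are not independent replicates, the log2 ratios of the sums correlated with the pools' fold changes at Pearson's r = 0.175, 0.221 and 0.289 (Spearman 0.179, 0.207 and 0.243) in that order.

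Each single bacterium was also set against the mean profile of each condition's pools over the 300 genes of highest variance. Of the NaCl shock bacteria 18 of 23 (78.3%, exact 95% interval 56.3 to 92.5) were closest to their own condition's pools, as were 15 of 27 anaerobic shock bacteria (55.6%, 35.3 to 74.5) and 9 of 19 late stationary bacteria (47.4%, 24.4 to 71.1). Among M2 libraries, which hold no late stationary single bacteria, these were 21 of 23 and 6 of 15.

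Pseudomonas pools showed 264 ± 106 detected genes (SD, n = 5, range 160 to 376) and single bacteria 102 ± 29.1 (n = 13, range 60 to 152). The pools held 31572 to 380827 counts and the single bacteria 28287 to 293514. Thinned to 28287 counts, pools showed 203 ± 66.9 genes and single bacteria 79.0 ± 24.4. The most abundant feature of the pools, EBG00001435499, stood at 50800 ± 20500 CPM and was detected in 5 of 5 pools and 11 of 13 single bacteria. PA1178 stood at 30700 ± 21600 CPM and was detected in 5 of 5 and 10 of 13. Gene names for Pseudomonas were not used here. Sums over pools and over single bacteria correlated across all 5807 genes at Pearson's r = 0.407 (Spearman 0.319), a sign that turned negative among genes with more than 10 reads in total (-0.212). With 1 condition there was no comparison between conditions.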

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

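The 3 tests on the number of detected genes, the comparison of row-sharing with same-condition libraries and the counts over other splits of the pools were chosen only after the results were seen. The tests on neighbouring wells, on source counts, on capped splits and on simulated counts were set beforehand.

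The 5 Salmonella libraries left out by the study entered no comparison, and their detected genes are listed here for that reason. That they hold counts at all says nothing about their quality. Anaerobic shock pool replicate 3 had 518 detected genes and 4888681 counts, and NaCl shock pool replicate 12 had 601 genes and 2952113 counts. Anaerobic shock pool replicate 11 had 299 genes. In it EBG00001133739 took 0.04% of the counts and another gene 28.4%. The single bacteria were anaerobic shock replicate 5 with 247 genes and NaCl shock replicate 22 with 329. No explanation was tested for these libraries.

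Late stationary pools showed fewer detected genes than NaCl shock pools, also where title prefix was held at M2 (204 against 683, two-sided exact permutation test, p = 0.00165). At 24369 counts per pool the difference held (55.8 against 277, permutation test, p = 2e-05). It also held with EBG00001133739 removed before thinning (57.3 against 287, permutation test, p = 2e-05). These values argue against title prefix, depth and that single feature as the whole cause. Less RNA per bacterium late in growth, poorer lysis and culture effects remain open, and none of them was tested.

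Libraries that shared a row letter, or a title prefix and a column number, held low counts of each other's dominant genes. The letters and numbers were read as plate wells, which is an inference. Of 74 genes with at least 50000 reads and at least 90% of them in 1 library, more than 5 reads were seen in 58.7% of libraries of the same prefix and column, 40.3% of the same prefix and row, 24.9% of the same row in another prefix, 7.91% of the same column in another prefix, 5.52% of the same prefix alone and 4.22% of libraries sharing nothing. Row-sharing libraries of another condition and prefix showed them 24.5 percentage points more often than same-condition libraries sharing neither (29.5% against 5.06%, interval 19.8 to 29.8), which argues against similar expression. Counts in sharing libraries rose with the source's count (Spearman 0.805 across 901 genes, 0.479 in other libraries), in line with reads assigned through a shared index, though physical carry-over could do the same, and spill to the neighbouring well is open (16.7 points more than at 3 or more columns away, 3.31 to 29.8).

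Random splits of the same pools also gave many genes past edgeR's threshold. Only 1 of 100 splits, the real one, gave as many as the 487 genes between late stationary and NaCl shock (highest other 256, median 187). The same held for the 410 between late stationary and anaerobic shock (1 of 100, highest other 333, median 267) and the 281 between NaCl and anaerobic shock (1 of 100, highest other 127, median 83). So an arbitrary grouping is excluded for the counts as a whole, but not for a given gene. Redrawn within title prefixes, the highest counts were 442, 410 and 146, and 3 of 100 draws reached the real count in late stationary against anaerobic shock. In the first 2 comparisons only M2 pools could change labels, since M1 and M3 each held 1 of the compared conditions. Much of the real grouping thus stayed in every draw, so the draws say little about prefixes there. Against anaerobic shock, with few M2 pools, a draw can also repeat the real split. limma-trend gave at most 1, 1 and 8 genes in other splits, and Fisher's exact test on detection at most 1, 1 and 0. Redrawn within title prefixes they gave more, limma-trend up to 210 of 234, 73 of 73 and 43 of 210 genes, and detection up to 332 of 370, 71 of 71 and 8 of 66.

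Over 20 of these splits, capping each gene at 10 times its median non-zero CPM brought the median number of called genes from 188 to 3.5, from 262.5 to 14 and from 81.5 to 0. The capped median was at most 5.33% of the uncapped one, which is consistent with a few pools holding most of a gene's reads. In the median called gene, the top pool held 45.8%, 46.3% and 50.3% of the reads in the 3 comparisons, and over 90% in 25, 24 and 15 called genes. In simulated negative binomial counts at most 3.93% of unchanged genes were called, which is a share of unchanged genes and not of the calls. This argues against independent negative binomial counts alone at the fitted dispersions. The simulated genes varied independently and their changes were balanced in direction. Shifts shared by many genes of a pool were thus not covered.

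No Pseudomonas pool lay apart from the other pools by Dixon's ratio, which chance passes in about 1 of 20 groups.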

How the results depend on the processing

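The settings chosen only after the data were seen are Fisher's exact test on detection, carried-over counts set to 0, capped counts, library size as the sole scaling, EBG features left out, thinning with M2 pools, list shares, direction by the share of bacteria, the filtered correlations and named genes without their largest pool; the others were planned. No paired analysis was possible because replicate numbers follow the order of the samples and tie no libraries of different conditions together. Keeping ribosomal and transfer RNA features gave no value, since 0 were identified.

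Between late stationary and NaCl shock pools, 487 genes passed edgeR's test (131 higher, 356 lower). The count was 2546 with no filter (770 and 1776), 200 with filterByExpr (63 and 137), 234 with limma-trend (25 and 209) and 302 with the 2 conditions alone (85 and 217). It was 305 with counts capped (27 and 278), 315 with counts also filtered for carry-over (10 and 305), and 164 of 227 tested genes by Fisher's exact test at 1 depth (2 and 162). It fell to 4 with a term for title prefix, 2 in M2 pools, 4 in capped M2 pools (1 and 3) and 13 by Fisher's exact test in filtered M2 pools (1 and 12). Chosen after their values were seen, these were glnQ (10.52), SL1344_1092 (12.33), pspA (9.00) and ruvB (6.19) with the prefix term, sifA (10.10) and EBG00001133739 (2.45) in M2 pools, and dps (-7.89), SL1344_1092 (6.65), fbaA (-6.00) and tuf SL1344_4085 (-5.98) in capped M2 pools.

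Between late stationary and anaerobic shock pools, 410 genes passed (163 and 247). The count was 1988 with no filter (788 and 1200), 198 with filterByExpr (80 and 118), 73 with limma-trend (10 and 63), 162 with the 2 conditions alone (53 and 109) and 206 with counts capped (17 and 189). Fisher's exact test gave 71 (1 and 70), 174 with carry-over filtered (1 and 173) and 69 of 227 tested genes at 1 depth (2 and 67). It was 2 with the prefix term, SL1344_1092 (12.03) and SL1344_4450 (9.97), and 2 in M2 pools, SL1344_0464 (11.73) and EBG00001133739 (1.68), all chosen after their values were seen. In M2 pools edgeR on capped counts gave 0 (109 at an unadjusted p under 0.05) and Fisher's exact test on filtered counts 0 (47 unadjusted).

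Between NaCl and anaerobic shock pools, 281 genes passed (199 and 82). The count was 2375 with no filter (1469 and 906), 112 with filterByExpr (70 and 42), 177 with the prefix term (119 and 58), 75 in M2 pools (47 and 28) and 162 without the shallowest pools (96 and 66). It was 70 with carry-over filtered (42 and 28), 78 capped (41 and 37), 37 with both (25 and 12) and 33 in capped M2 pools (15 and 18). Fisher's exact test gave 66 (52 and 14), 89 filtered (70 and 19), 29 at 1 depth (18 and 11) and, in filtered M2 pools, 0 (43 unadjusted), where edgeR on capped counts gave the 33. Fewer genes are tested under filterByExpr and carry-over filtering, and fewer pools under M2. Fisher's exact test at 1 depth covers fewer genes (227) and fewer pools. The cause was not tested otherwise. The carry-over filter set 0.242% of reads to 0 and left 494 genes to test. Most columns of a prefix held 1 condition, so carry-over could raise the likeness of libraries of a condition.

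With the prefix term 355 of 356 lower and 44 of 131 higher genes kept their sign between late stationary and NaCl shock, and 233 of 247 and 75 of 163 between late stationary and anaerobic shock. The SEs rose, so the fall in these counts does not by itself make prefix the cause. The kept signs cannot clear prefix either, since the term moved most genes down. With it 619 of all 712 genes were negative against NaCl shock (484 without) and 522 against anaerobic shock (421 without). Whether prefix is a cause for the lower genes cannot be told.

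The other totals stayed within 1.5 times, but not always the number in 1 direction. Against NaCl shock DESeq2 gave 460 genes (82 and 378), Fisher's exact test 370 (2 and 368), or 365 filtered (2 and 363), and edgeR with carry-over filtered 339 (18 and 321). Against anaerobic shock DESeq2 gave 280 (65 and 215), edgeR with carry-over filtered 337 (32 and 305) and with counts also capped 303 (13 and 290). Between the shocks limma-trend gave 210 (156 and 54) and library size as the sole scaling 121 and 76. Among the totals, in the order of the comparisons above, were 456, 401 and 233 with TMMwsp and 479, 404 and 274 without EBG features. With library size as the sole scaling they were 475, 437 and 197, and the share higher went from 26.9% to 11.6%, from 39.8% to 16.7% and from 70.8% to 61.4%. The median log2 fold change of all genes was -3.07, -1.09 and 1.42 with TMM, -4.31, -3.24 and 0.72 with that scaling, -3.39, -1.94 and 0.71 with poscounts and -2.43, -0.93 and 0.82 with TMMwsp. Directions are therefore relative to the scaling.

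Of 73 named calls, 55 kept their sign in every alternative that tested them. The threshold was passed by 33 in every alternative that tested them, the prefix term and M2 alone aside. A call that an alternative did not test counted as kept. Only 56 of the 73 were tested with carry-over filtered, 47 under filterByExpr and 54 in M2 pools. Where tested, none reversed between NaCl and anaerobic shock. The log2 fold changes below reversed, and the cause was not tested. Without the pool of its largest count frdA was -2.03 against NaCl shock, and against anaerobic shock tuf was -1.01, aceE -1.77 and putA -0.57. In that setting 59 of the 73 calls passed, 10 did not and these 4 reversed. Late stationary against NaCl shock: with the prefix term rpoC was -4.99, malE -2.94, frdA -2.84, glpD -3.66 and dmsB -4.08. In M2 pools rpoC was -4.38, malE -2.14, frdA -1.64 and glpD -2.64. In capped M2 pools rpoC was -3.34, malE -2.57, frdA -2.25, glpD -3.0, tcp -0.08 and dmsB -4.85. With limma-trend rpoC was -2.39 and glpD -1.26, with counts capped rpoC -0.67 and frdA -0.16, with counts also filtered glpK -0.35 and glpD -0.48, and with library size as the sole scaling frdA -0.69.

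Late stationary against anaerobic shock: with the prefix term rpoC was -3.90, glpD -0.27, tuf -3.84, aceE -2.55, sdhC 0.78, putA -0.04, fumC -5.33 and ftsH -0.22. In M2 pools rpoC was -3.84, glpD -1.13, tuf -4.10, aceE -2.32 and sdhC 1.31. In capped M2 pools rpoC was -2.64, glpD -1.69, tuf -4.86, aceE -2.25, sdhC 1.12, putA -0.53 and fumC -1.52. With DESeq2 tuf was -0.77, aceE -1.17 and putA -0.78, with limma-trend tuf -1.49 and with carry-over filtered tuf -1.39. With library size as the sole scaling tuf was -1.84, aceE -0.62 and nadR -0.28. With counts capped glpK was -0.01, aceE -0.77 and rpsB -0.53, and with counts also filtered glpK -0.78, tuf -1.58, putA -0.16 and rpsB -0.09.

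The difference in detected genes between NaCl and anaerobic shock pools was 166 in M2 pools (adjusted p = 0.0558, exact permutation test), no longer past the threshold. In thinned M2 pools it was 88.1, and that between late stationary and anaerobic shock was -96.8 (both adjusted p = 0.0545, exact permutation tests). The other comparisons of detected genes kept their direction and their side of the threshold. Of 45 set tests 7 passed, against 2 with an estimated correlation. In M2 pools, where the amino acid list had too few tested members, 3 passed. Of 60 tests of list shares 9 passed, against 3 in M2 pools and 15 in M2 pools with carry-over filtered. The filter itself may account for part of the 15, which was not tested.

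Of late stationary bacteria 73.7% were closest to their own pools over the called genes, against 47.4% over the genes of highest variance. The called genes were picked on these pools. In M2 libraries with carry-over filtered, 78.9% of 38 bacteria were, against 60.9% of 69 in all. These are not alike, since M2 holds no late stationary bacteria, and M2 alone gave 71.1%. By the share of bacteria, genes sharing the pools' direction were 68.3% for late stationary against NaCl shock, or 76.2% filtered (63.5% by sums), and 66.7% against anaerobic shock (60.1% by sums). The filtered value is 244 of 265 genes lower in late stationary pools but 19 of 80 higher ones, and that against anaerobic shock 186 of 221 and 52 of 136, so most of the higher genes went the other way. These shares were taken at full depth and late stationary bacteria were the shallowest, so the split cannot be told apart from depth. Pseudomonas showed 488 genes per pool and 289 per single bacterium at 1 read or more. Leaving out each pool gave 236 to 290 genes per pool and a correlation of 0.381 to 0.408. Among genes of more than 10 reads the correlation was -0.212, or -0.334 thinned. That version was computed first and replaced by all genes after its value was seen. Selecting on the sum pushes it down and genes at 0 push it up, so nothing is drawn from its sign. Depth kept 10 late stationary bacteria, which held under 24369 counts, out of the comparison at that depth.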

Other observations

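The values below on SPI-1 genes, on list shares and on genes with constant counts were chosen only after the data were seen; the set tests were planned.

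SPI-1 invasion genes were too sparse to be tested as a set. In single bacteria, with counts that may have been carried over set to 0, the regulator gene hilC was detected in 12 of 19 late stationary (63.2%, exact 95% interval 38.4 to 83.7), 2 of 23 NaCl shock and 2 of 27 anaerobic shock bacteria. The effector gene sopA was detected in 14 of 19 (73.7%, 48.8 to 90.9), 5 of 23 and 8 of 27. In pools hilC was detected in 3 of 20, 0 of 19 and 2 of 18, and sopA in 7 of 20, 3 of 19 and 7 of 18. hilD was detected in 0 of 20, 2 of 19 and 4 of 18 pools, and sicA in 1 of 20, 4 of 19 and 1 of 18. Median counts where detected in late stationary bacteria were 11.5 for hilC and 11 for sopA, close to the limit of 5. All late stationary single bacteria carry prefix M1, so condition and prefix cannot be told apart for them. hilC was not detected in any of the 16 late stationary M1 pools, and its 3 positive pools were M2. This goes against reading its counts in single bacteria as expression. sopA did not show this pattern, with 6 of its 7 positive late stationary pools in M1. The list made up 0.773% of the genes detected in late stationary pools, 0.416% after NaCl shock and 0.462% after anaerobic shock, and these did not differ past the threshold (adjusted p = 0.161 and 0.275, permutation tests). With carried-over counts set to 0, the shares were 1.09%, 0.425% and 0.52% (adjusted p = 0.0506 and 0.111). In M2 pools so treated, late stationary pools passed against NaCl shock (2.0% against 0.393%, n = 4 and 16, adjusted p = 0.0324, exact permutation test) and not against anaerobic shock (adjusted p = 0.162). Thinned, the direction against NaCl shock turned (0.403% against 0.477%, adjusted p = 0.898).

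Ribosomal protein genes made up 3.17% of the genes detected in late stationary pools as deposited, 4.34% after NaCl shock and 3.32% after anaerobic shock. Late stationary pools differed from NaCl shock pools (adjusted p = 0.0393, permutation test) and not from anaerobic shock pools (adjusted p = 0.817). With carried-over counts set to 0 the shares were 1.41%, 4.65% and 3.19% (adjusted p = 0.0004 and 0.0135, and 0.0386 between the shocks), and thinned 1.41%, 5.66% and 3.38%, where NaCl shock pools passed against late stationary (0.0004) and anaerobic shock pools (0.0266). Among M2 pools as deposited they were 4.56%, 4.07% and 4.75%, and no difference passed. In M2 pools with carried-over counts set to 0, they were 2.2%, 4.39% and 5.01%, and late stationary pools passed against both (adjusted p = 0.0269 and 0.0484). Chaperone genes made up 1.04%, 1.25% and 1.35% as deposited, and late stationary pools did not differ from the others (adjusted p = 0.473 and 0.344). With carried-over counts set to 0 they made up 0.303%, 1.21% and 1.28% (adjusted p = 0.00072 and 0.0006). The filter took late stationary pools from 192 to 89.7 detected genes, NaCl shock pools from 637 to 533 and anaerobic shock pools from 424 to 343. It can also remove real low counts. Part of any lower filtered share in late stationary pools may come from the filter, which was not tested.

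Other lists also passed this test of shares as deposited. Envelope stress genes made up 1.08% of the genes detected in late stationary pools against 0.516% after NaCl and 0.443% after anaerobic shock (both adjusted p = 0.0393). This held with carried-over counts set to 0 (adjusted p = 0.0295 and 0.0216) and thinned (0.0408 and 0.0413), but in M2 pools the direction turned, at 0.355% against 0.493% and 0.672% (0.618 and 0.522). Outer membrane genes made up 1.36%, 0.79% and 1.13%, which passed for late stationary against NaCl shock (adjusted p = 0.0264) and between the shocks (0.0423). With carried-over counts set to 0 neither passed (0.954 and 0.111), nor thinned (0.393 and 0.374), while in M2 pools the first did and the second did not (0.0412 and 0.438). Osmoprotection genes made up 1.3% in late stationary against 0.73% in anaerobic shock pools (adjusted p = 0.0423). This passed with carried-over counts set to 0 (0.002), but not thinned (0.573) or in M2 pools (0.436). proW, whose counts did not rise with depth, is in this list and its part in the share was not separated, so the difference is not read as expression. The anaerobic list was higher in late stationary than in NaCl shock pools (3.75% against 2.22%, adjusted p = 0.0264), but not with carried-over counts set to 0 (0.82), thinned (0.568) or in M2 pools (0.41).

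Some lists passed the test of shares only in other settings. Thinned, flagellar genes made up 1.37% after NaCl and 2.25% after anaerobic shock (adjusted p = 0.0413). Chaperone genes made up 0.68% in late stationary and 1.8% in NaCl shock pools (0.0386). With carried-over counts set to 0, ATP synthase genes made up 0.249% and 0.7% (0.0386). In M2 pools iron uptake genes made up 0.0828% in late stationary and 0.772% in NaCl shock pools (0.0412). In M2 pools with carried-over counts set to 0, late stationary pools were lower in flagellar, translation factor and chaperone genes than both shocks (adjusted p from 0.0124 to 0.0484) and in ATP synthase and iron uptake genes than NaCl shock (both 0.0247). There the shocks also differed in flagellar (1.55% and 2.27%) and iron uptake genes (0.839% and 0.273%, both 0.0269).

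In the set tests, the lists not described in the comparisons gave nothing past camera's threshold. The translation factor, envelope stress, outer membrane, ATP synthase, purine and pyrimidine, cold shock, nucleoid and amino acid lists had 3 to 7 tested members each. For late stationary against NaCl shock their adjusted p-values were 0.237, 0.237, 0.494, 0.494, 0.858, 0.367, 0.831 and 0.94 in that order. For late stationary against anaerobic shock they were 0.494, 0.494, 0.494, 0.494, 0.693, 0.846, 0.981 and 0.846. For NaCl against anaerobic shock they were 0.494, 0.826, 0.94, 0.997, 0.494, 0.494, 0.846 and 0.997. The osmoprotection (3 higher, 1 lower of 8), aerobic respiration (10 and 8 of 25), flagellar (2 and 6 of 16) and chaperone (1 and 1 of 10) lists did not pass between late stationary and anaerobic shock (adjusted p = 0.104, 0.514, 0.494 and 0.662). Between NaCl and anaerobic shock the flagellar (1 and 3) and chaperone (3 and 1) lists did not pass (adjusted p = 0.171 and 0.237).

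Some widely seen genes did not rise with depth. Of 27 genes seen in at least 70% of the 126 libraries, 7 had a median count no higher in the 63 deeper libraries than in the 63 shallower ones. They were nrfEF (264 in shallower and 125 in deeper libraries), fldA (212 and 125), SL1344_1696 (44 and 23), kbl (16 and 14), nadR (19 and 12), proW (20 and 9) and golT (10 and 8). ompA, by contrast, had medians of 136 and 21673. Depth goes with title prefix. Within each prefix the medians of these genes were also no higher in the deeper libraries, except golT in M2 (8 and 12). In M3 this does not set them apart, since gapA (429 and 98), fusA (180 and 5) and others also fell there, while ompA rose (791 and 36407). Depth in M3 also went with library kind, at a median total of 57002 in anaerobic shock pools and 1361801.5 in single bacteria. In M1 rpsL fell as well (25 and 11.5). Where these counts come from was not tested, and contaminating or primer-derived reads are not excluded. The limit of 70% was set to include genes already seen.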
